A study of Sorghum bicolor with 395 samples.

How the data were processed

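Leaves and roots of sorghum lines RTX430 and BTX642 were sampled from numbered field plots under control watering, drought before flowering and drought after flowering. Per the labels, polyadenylated RNA was made into libraries with a stranded Illumina TruSeq kit. The submitters' processing notes name HISAT2 2.1.0 and featureCounts, and their settings are not given in the sources used here. The gene models that go with the tables carry annotation version 3.1 per the file headers, and all coordinates are from those models.

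The deposited tables, 1 for leaves and 1 for roots, hold a normalized signal per gene and library with decimals. In each library the deposited values were whole multiples of the smallest value above 0, for 100% of values within 0.01, so whole reads were recovered as that multiple. All libraries of a table shared the same upper quartile, 746.66 in leaves and 941.76 in roots, so the deposited values are read counts per gene divided by 1 upper-quartile factor per library. Each table was normalized on its own, and tests were made within a table only. There were 21808 genes in the leaf table and 23830 in that of roots, each with over 20 reads in at least 4 libraries, so genes under that level were not analysed here. The leaf table's value columns matched 197 libraries and the root table's 198. The description of the leaf library of control BTX642 plot 19 at day 119 names the root table, but its column stands in the leaf table, and it was used as a leaf library. The top 10 genes took 3.85 to 11.1% of the reads of a leaf library and 2.4 to 5.32% of those of a root library. Libraries of 1 group differed by far more than sampling noise: over 177 leaf and 176 root pairs the lowest chi-square per gene was 8.39 and 6.14, so no library was counted as a repeat of another.

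Choices of groups, tests, lists and alternatives were made before the data were examined, except where stated. The main test was limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8), on log2(normalized value + 1), over genes with a mean of at least 10 (19945 in leaves, 22039 in roots). Fold changes are on that scale, which understates the change of genes near 0. For each tissue 1 model held a mean for each combination of genotype, regime and age, with plot as a random block. The correlation of libraries of 1 plot, estimated from 2000 genes, was 0.154 in leaves and 0.0931 in roots, with 119 residual degrees of freedom. Moderated statistics with a mean-variance trend were adjusted by the method of Benjamini and Hochberg within each comparison, with a threshold of 0.05. All adjusted p-values in the text are limma's unless another tool is named. Plots are separate parts of a single field and were sampled repeatedly. The p-values measure the spread between libraries of different plots at the same age, with 1 plot correlation for all genes. They do not measure the spread between fields or years. Standard deviations are over the means of plots.

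The labels give ages and regimes but no dates of irrigation. From knowledge of the trial, the preflowering window was set to days 21, 28, 35, 42 and 56, with day 63 on its own, days 70, 77, 84, 91, 105 and 119 as the later days, and days 70, 77, 91, 105 and 119 as the postflowering window. Days 49, 98 and 112, and day 84 of the postflowering plots, had 1 plot per group and stayed out of the windows. Preflowering RTX430 leaves at day 105 also had 1 library, from plot 5. Day 105 stayed among the later days, but the preflowering plots were not tested at that age alone. The hour of collection is also not in the labels, and clock genes can move with it. The genes followed from day 56 to day 63 were chosen at day 42, a choice made after the data were seen, since genes chosen at day 56 would fall back by that choice alone. Age under control compared days 91, 105 and 119 with days 14, 21 and 28. The single ages given for named root genes after day 63 were chosen after their values were seen.

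The tables give gene identifiers only. None of them could be matched to the reference gene table (32945 entries, 0 matched identifiers, 34211 gene models), so the planned lists that rest on gene descriptions were not built, and the rule for naming the genes with the largest changes was narrowed. Per comparison, at most 2 identifiers that rose and 2 that fell are given, from genes called in each genotype on its own with the same sign and a mean of at least 50 (for differences between genotypes, genotype and age, genes called in that comparison). Gene names come from identifiers published for sorghum and known beforehand, not from the files, and were not checked against an annotation. The 12 identifiers fixed before the data were examined are CYP79A1 (Sobic.001G012300), CYP71E1 (Sobic.001G012200) and UGT85B1 (Sobic.001G012400) in the dhurrin list, PEPC (Sobic.010G160700), PPDK (Sobic.009G132900), NADP-ME (Sobic.003G036200) and NADP-MDH (Sobic.007G166300) in the carbon fixation list, LHY (Sobic.007G047400), TOC1 (Sobic.004G216700) and GI (Sobic.003G040900) in the clock list, and P5CS2 (Sobic.003G356000) and DHN1 (Sobic.009G116700). A further 22 were added after the gene identifiers were known and before their values were seen, of which 20 were tested in leaves and 13 in roots, and not all of them are reported here. Those named in the text are RbcS (Sobic.005G042000), CA (Sobic.003G234200), MATE2 (Sobic.001G012600), PRR37 (Sobic.006G057866), GHD7 (Sobic.006G004400), EHD1 (Sobic.001G227900), CN8 (Sobic.009G199900), CN12 (Sobic.003G295300), CN15 (Sobic.010G045100), PHYB (Sobic.001G394400), PHYC (Sobic.001G087100), DW1 (Sobic.009G229800), CAD2 (Sobic.004G071000), 4CL (Sobic.004G062500), CCoAOMT (Sobic.010G052200), DW3 (Sobic.007G163800), TST2 (Sobic.004G099300) and VIN1 (Sobic.004G004800). As a check of these names, PPDK, PEPC, CA and NADP-ME held ranks 1 to 4 of all leaf genes by mean, and the dhurrin genes were neighbours on chromosome 1.

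Lists of at least 3 tested members were compared with all other genes by limma's cameraPR on the moderated statistics, with a preset correlation of 0.01 between genes, again with the correlation estimated from residuals and again on ranks. The 3 lists and 14 comparisons in 2 tissues gave 84 tests, adjusted over the 3 lists of each comparison. With so few members these tests carry little weight. Genes enriched in 1 tissue were those with a mean over 64-fold that of the other tissue under control, a choice made after the data were seen. Runs of neighbouring genes were sought in windows of 10 consecutive tested genes, counting genes called and at least 2-fold changed, against 1000 shuffles of the calls over the genes.

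Alternatives were other pseudocounts, no filter, median-of-ratios rescaling, no block, a block of neighbouring plot numbers, means per plot, only the groups compared, other ages, each plot left out in turn, and edgeR 4.0.16 (quasi-likelihood test, no block) on the recovered reads. Added after the data were seen were fits without 3 libraries of under 6 M reads and 1 root library of mixed genotype, a postflowering window of days 70, 77 and 91, windows of 20 genes, and splits of the plots within sets of neighbouring plot numbers. On simulated data with 100 genes changed per fold size, the leaf preflowering test over 19945 genes recovered 74 of 100 genes changed 1.5-fold and 92 changed 2-fold, with 5 unchanged genes called. The root preflowering test over 22039 genes recovered 73 and 94, with 8 unchanged genes called. For the postflowering comparison, the leaf test recovered 64 and 88, with 8 unchanged genes called, and the root test 65 and 93, with 13. The simulation drew plot effects for each gene on its own, so these false calls do not cover plot differences that many genes share. Splits of the real postflowering and control plots at day 63 called up to 1437 leaf and 1482 root genes. In 20 simulations with a planted run over 22039 genes the window test found 20, and it passed 0 of 20 without one. The list test passed 200 of 200 lists of 4 genes shifted by 3 SD and 14 of 200 unshifted ones. Its simulated genes were independent, while the estimated correlation within a list was as high as 0.767 (dhurrin genes in leaves). This check therefore does not cover lists of correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.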

Results

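The series followed gene expression in leaves and roots of field-grown sorghum (Sorghum bicolor) under control watering, under drought before flowering and under drought after flowering. It asks which genes respond to each drought and whether the responses differ between the genotypes. The plants were RTX430, a line known for tolerance of drought before flowering, and BTX642, a stay-green line known for tolerance of drought after flowering. Polyadenylated RNA was sequenced in 395 libraries, 197 of leaves and 198 of roots, at 16 ages from 14 to 119 days. Each genotype and regime had 3 plots, 18 in all, and each plot was sampled again at most ages. Of the 157 combinations of tissue, genotype, regime and age, 115 held 3 libraries, 8 held 2 and 34 held 1. The libraries of one combination came from separately numbered plots in a single field season. The p-values measure the spread between such libraries, pooled over all combinations. Repeated ages of a plot were tied by 1 correlation shared by all genes, so lasting plot differences of a gene beyond it are not fully covered. Leaf libraries held 1.87 to 53.9 M whole reads over the tabled genes (median 19.4), and root libraries 3.67 to 55.3 M (median 20.95). The medians of the tissue, genotype and regime groups lay between 16.85 M in postflowering RTX430 leaves and 22.3 M in preflowering BTX642 roots.

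In leaves, drought before flowering raised DHN1, the gene of a dehydrin that accumulates in drying cells (Sobic.009G116700, chromosome 9, 45915615 to 45916682). Over days 21 to 56 DHN1 averaged 1319 ± 161 normalized counts in droughted RTX430 plots and 65.3 ± 30 in control plots (SD, n = 3 plots each). In BTX642 it averaged 3312 ± 608 against 282 ± 208. That control mean rests on day 28, at 1599 (n = 2, without plot 11), while the other days averaged 46.8 to 116. Its log2 change, as the mean of both genotypes, was 4.36 (SE 0.36; limma, adjusted p = 5.13e-20). P5CS2, an enzyme of proline synthesis, rose by 1.03 (SE 0.15), and RbcS, the small subunit of Rubisco, fell by 0.56 (SE 0.11; limma, adjusted p = 2.13e-05). EHD1, an activator of florigen genes in grasses, fell by 1.18 (SE 0.26). CN15, CN12 and CN8, members of the family of the florigen FT, fell by 1.68 (SE 0.26), 1.02 (SE 0.25) and 0.95 (SE 0.35). PRR37, a repressor of flowering in long days, fell by 0.68 (SE 0.19), and PHYB, a red-light receptor, fell by 0.66 (SE 0.09; limma, adjusted p = 2.29e-09). Of the 4 measured genes of the C4 carbon fixation list, 2 fell over all genes and 2 adjusted over the list alone: PPDK, which regenerates the acceptor of the C4 cycle, fell by 0.28 (SE 0.11), and NADP-ME, its decarboxylase, fell by 0.27 (SE 0.09). Of the 3 genes for the synthesis of dhurrin, the cyanogenic glucoside of sorghum, CYP71E1 alone passed and rose by 0.61 (SE 0.24), also adjusted over the list alone. Of the 3 circadian clock genes, TOC1 alone passed and fell by 0.53 (SE 0.18), also adjusted over the list alone. Set against all other genes, no list passed (limma's camera test, adjusted p = 0.326 for each of the 3). Leaving out 1 plot ended the calls of PPDK (plot 1, 2, 11, 12, 13, 14, 17 or 18; adjusted p up to 0.131), NADP-ME (1, 2 or 14; up to 0.0571), CYP71E1 (5, 6, 12, 19 or 20; up to 0.162) and CN8 (1, 12, 13, 14 or 17; up to 0.081). Without day 21 TOC1 (adjusted p = 0.0536), CN8 (0.129), PPDK (0.163) and NADP-ME (0.0729) lost their calls, and with 1 mean per plot PPDK (0.263), NADP-ME (0.0604) and CYP71E1 (0.0516).

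The largest leaf rises before flowering among genes called in both genotypes were in Sobic.009G215700 (chromosome 9, 56036800 to 56038103), at 6.38 (SE 0.47), and Sobic.006G007300 (chromosome 6, 1082714 to 1083434), at 6.13 (SE 0.40). The largest falls were in Sobic.001G369200 (chromosome 1, 65765769 to 65769600), which fell by 3.11 (SE 0.31; −4.01 by edgeR with an adjusted p of 1, as a combination of genotype, regime and age held no read), and Sobic.002G407200 (chromosome 2, 75652189 to 75654103), which fell by 2.60 (SE 0.27). Of 19945 tested genes, limma called 8210 at an adjusted p of 0.05, 4652 higher and 3558 lower, and 1041 of them changed at least 2-fold (544 higher, 497 lower). The share of higher genes among the calls, 56.7%, became 49.2% after median-of-ratios rescaling, and edgeR called 4796 higher and 5586 lower. In RTX430 alone 3573 genes were called, and in BTX642 alone 5178. The ages within the window were not alike: day 28 had 281 calls and day 56 had 8667. Without plot 12, 13 or 18 the RTX430 count was 2143, 1757 or 1855, and without plot 17 the BTX642 count was 3025, while edgeR called 6447 and 7986. The day 28 count was 153, 18, 181, 20, 113, 57 and 132 without plots 1, 2, 12, 13, 14, 17 and 18 in turn, but 568 with a block of neighbouring plots and 905 with only the groups compared.

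In roots, drought before flowering raised the same dehydrin gene. DHN1 averaged 9792 ± 2694 normalized counts in droughted RTX430 plots against 939 ± 383 in control plots, and 42891 ± 8749 against 7696 ± 5913 in BTX642 (SD, n = 3 plots each). Control means were highest at day 28, at 3501 in RTX430 and 31599 in BTX642, and at day 56 they were 84.6 and 49. Its mean log2 change was 5.98 (SE 0.34; limma, adjusted p = 3.94e-33). P5CS2 rose by 2.26 (SE 0.11) and TST2, a vacuolar sugar transporter, by 0.67 (SE 0.09), whereas VIN1, a vacuolar invertase that splits sucrose, fell by 1.15 (SE 0.22). All 3 dhurrin genes rose over all genes and adjusted over the list alone: CYP79A1, the entry enzyme of the pathway, by 1.71 (SE 0.27; limma, adjusted p = 1.76e-08), CYP71E1 by 0.67 (SE 0.15) and UGT85B1, which adds the glucose, by 0.72 (SE 0.18). MATE2, a vacuolar importer of dhurrin, rose by 0.70 (SE 0.10). The lignin synthesis enzymes 4CL, CCoAOMT and CAD2 fell by 0.65 (SE 0.09), 0.69 (SE 0.14) and 0.49 (SE 0.11). Of the 4 carbon fixation genes, PPDK fell by 2.37 (SE 0.15), from 5352 ± 708 to 1163 ± 201 normalized counts in RTX430 and from 5018 ± 979 to 501 ± 109 in BTX642. NADP-ME also fell, by 0.46 (SE 0.21), and NADP-MDH, a malate-forming enzyme, rose by 1.17 (SE 0.11), so that 1 rose and 2 fell over all genes and adjusted over the list alone. Of the 3 clock genes 2 rose by both adjustments, TOC1 by 0.80 (SE 0.11) and GI by 0.55 (SE 0.16). Set against all other genes no list passed (limma's camera test, adjusted p = 0.517 for each of the 3). NADP-ME lost its call without plot 1, 5, 6, 12, 13 or 19 (adjusted p up to 0.117) and without the libraries of low depth or mixed genotype (adjusted p = 0.054).

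The root response before flowering reached 16844 of 22039 tested genes (limma, adjusted p of 0.05), 8616 higher and 8228 lower. The share of higher genes, 51.2%, became 46.4% after median-of-ratios rescaling, and edgeR called 8489 higher and 9064 lower. The genes that changed at least 2-fold were mostly lower, with 1395 higher and 2863 lower. The largest rises were in Sobic.006G093500 (chromosome 6, 46339260 to 46343909), at 6.94 (SE 0.41), and Sobic.001G438000 (chromosome 1, 71623555 to 71624809), at 6.21 (SE 0.40). The largest falls were in Sobic.002G023200 (chromosome 2, 2132809 to 2133609), which fell by 7.92 (SE 0.42), and Sobic.005G215766 (chromosome 5, 70171246 to 70172126), which fell by 7.05 (SE 0.36). By genotype, 14560 genes were called in RTX430 and 14542 in BTX642.

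Called genes in preflowering plots increased from day 21 to day 56 in roots, from 3601 to 15216, and dropped to 7715 at day 63. In leaves 3533 genes were called at day 21, 281 at day 28, 8667 at day 56 and 3105 at day 63. Day 63 lies after the days assigned here to the preflowering drought. Root DHN1 in preflowering RTX430 plots averaged 11372 ± 2796 normalized counts at day 56, 2612 ± 1590 at day 63 and 470 ± 134 at day 70 (SD, n = 3 plots), and in control plots 84.6 ± 68.6, 16.3 ± 9.49 and 14.9 ± 10.1. From day 56 to day 63 the leaf difference from control fell by 4.83 for DHN1 (SE 0.81) and by 1.71 for P5CS2 (SE 0.34), and rose by 1.79 for RbcS (SE 0.25; limma, adjusted p = 1.66e-08). In roots it fell by 1.75 for P5CS2 (SE 0.29) and by 2.41 for TOC1 (SE 0.28), and rose by 3.05 for VIN1 (SE 0.59) and by 1.27 for 4CL (SE 0.23). Of 1675 leaf genes that were at least 2-fold changed and called at day 42, whose libraries do not enter the change, 1127 had a called change toward control from day 56 to day 63 and 3 one away from it. The matching root numbers were 6508, 4587 and 27. In all, the change between the days was called for 6179 leaf genes and 11687 root genes. The leaf calls split 2492 higher to 3687 lower, a share of 40.3% higher that became 51.6% after median-of-ratios rescaling, and edgeR called 2834 higher and 2262 lower. Leaf calls were 2178 and 2237 at day 21 without plot 13 or 14, and 1907 at day 63 without plot 14. At day 28 they were 153, 18, 181, 20, 113, 57 and 132 without plots 1, 2, 12, 13, 14, 17 and 18, 568 with a block of neighbouring plots and 905 with only the groups compared. Root calls at day 21 were 2259 and 2348 without plot 18 or 20.

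**Figure D1:**
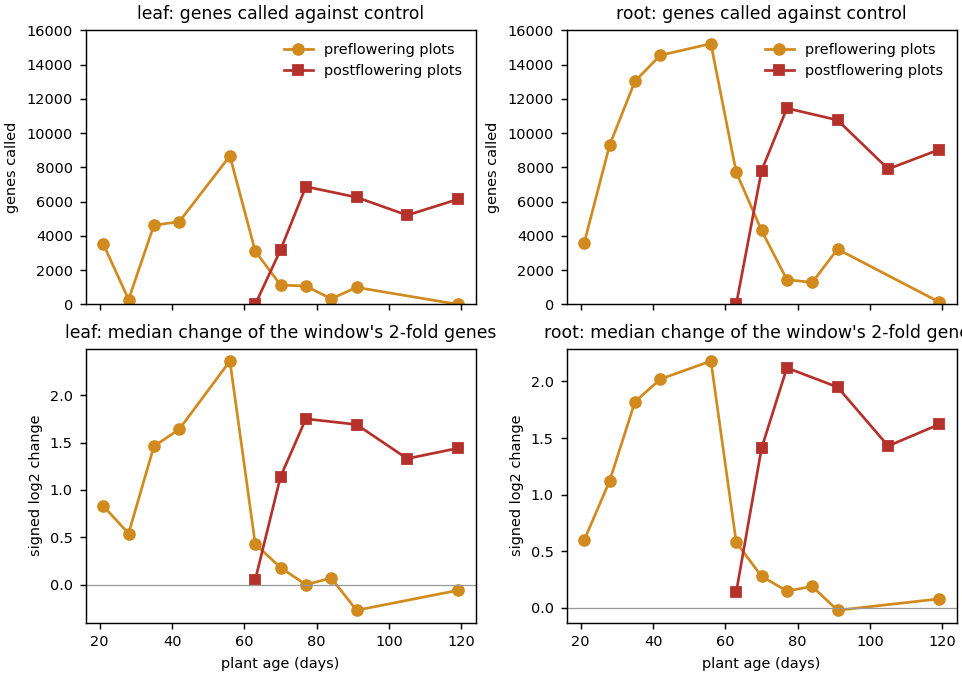
Genes called against control at each age (upper panels, counts of genes) and the median signed log2 change of the genes that changed at least 2-fold over the window of each drought (lower panels), against plant age in days, for leaf and root. Root calls in preflowering plots rise from 3601 at day 21 to 15216 at day 56 and stand at 7715 at day 63, while the postflowering plots start at 0 calls on day 63.

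At day 63 itself, leaves of the preflowering plots stood above control for RbcS, by 1.22 (SE 0.19; limma, adjusted p = 8.13e-07). RbcS averaged 42746 ± 4079 normalized counts against 22637 ± 5333 in RTX430 and 55030 ± 12852 against 19032 ± 673 in BTX642 (SD, n = 3 plots each). VIN1 stood 2.50 above control (SE 0.67), PEPC, the first carboxylase of the C4 cycle, 0.62 (SE 0.19) and DHN1 2.13 (SE 0.62). Of the 4 leaf carbon fixation genes 1 rose over all genes and 4 adjusted over the list alone, and the list passed against all other genes (camera, adjusted p = 0.0251), though not with an estimated correlation (adjusted p = 0.294). In roots DHN1 stood 7.73 above control (SE 0.65), P5CS2 1.41 (SE 0.21) and VIN1 1.54 (SE 0.42), while PPDK had fallen by 3.34 (SE 0.28) and TOC1 by 1.21 (SE 0.20). The 3 root dhurrin genes were all higher, by both adjustments, with CYP79A1 at 1.79 (SE 0.52). Of the 4 root carbon fixation genes 1 fell by both adjustments, and the list passed with the preset correlation (adjusted p = 0.016) but not with an estimated one (adjusted p = 0.101) nor on ranks (adjusted p = 0.124). In total 3105 leaf genes and 7715 root genes were called, with 1907 in leaves without plot 14. Leaf calls were lost without 1 plot for VIN1 (plot 6, adjusted p = 0.056), DHN1 (plots 5 and 6, 0.0542 and 0.066) and PEPC (plot 5, 12, 14 or 19, up to 0.0626), and with only the day 63 libraries for VIN1 (0.0813) and PEPC (0.172).

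As a mean over days 70 to 119 the preflowering plots differed from control, though fewer genes were called at the last age, without a steady decline. Calls were 1129 in leaves and 4319 in roots at day 70, 1071 and 1445 at day 77, 326 and 1283 at day 84, 995 and 3224 at day 91, and 2 and 149 at day 119. Leaf CYP79A1 averaged 431 ± 203 normalized counts in preflowering RTX430 plots against 71.5 ± 11.2 in control, and 562 ± 47.8 against 111 ± 47.2 in BTX642 (SD, n = 3 plots each), a log2 change of 2.13 (SE 0.37; limma, adjusted p = 7.83e-06). UGT85B1 rose by 0.85 (SE 0.27), CYP71E1 by 0.76 (SE 0.23) and MATE2 by 0.61 (SE 0.13). The leaf dhurrin genes thus rose 3 of 3, over all genes and adjusted over the list alone, and the list passed against all other genes (camera, adjusted p = 1.50e-04) and with an estimated correlation (adjusted p = 0.0302). CN8 and CN12 rose in leaves by 1.44 (SE 0.34) and 1.25 (SE 0.24). In roots the 3 dhurrin genes also rose by both adjustments, CYP79A1 by 1.09 (SE 0.26), and that list passed with the preset correlation (adjusted p = 0.00518) but not with an estimated one (adjusted p = 0.121). Among the ages tested singly, root CYP79A1 was called at days 84 and 91 only, at 2.18 (SE 0.55) and 2.73 (SE 0.52), and stood at −0.55 (SE 0.52) at day 119. Root DHN1 stood 1.67 above control (SE 0.33), with calls at days 70 and 77, at 5.06 (SE 0.65) and 3.65 (SE 0.65), and none at day 84, at 1.90 (SE 0.69; adjusted p = 0.0818), or at day 91, at −0.45 (SE 0.65). VIN1 in roots stood 1.52 above control (SE 0.21), while PPDK fell by 1.26 (SE 0.14) and TOC1 by 0.88 (SE 0.10). At day 119 alone none of the genes named here was called in its tissue. Among genes enriched in leaves over roots under control, measured in the roots of these plots, 11 of 194 rose and 54 fell, with a median of −0.16. In total 1665 leaf genes were called, 864 higher and 801 lower (1455 and 2126 by edgeR), and 5265 root genes, 2237 higher and 3028 lower. The share of higher root genes, 42.5%, became 49.8% after median-of-ratios rescaling. For the leaf count, 8 of 100 splits of the plots into groups of the same sizes called as many genes, so these do not exclude chance. With plots exchanged only within sets of neighbouring plot numbers, and the sets in the model, it was 1 of 32 (2901 genes, highest other 973). Without plot 13 the count was 1107. Leaf calls at day 70 were 679, 618, 579 and 728 without plots 1, 13, 14 and 17, and those at day 77 were 659, 659, 680, 655 and 707 without plots 13, 14, 17, 18 and 19. Those at day 84 were 191, 203, 153, 164, 211, 205, 500 and 564 without plots 1, 11, 13, 14, 17, 18, 19 and 20, those at day 91 were 281, 381, 394, 267 and 355 without plots 1, 2, 13, 14 and 18, and those at day 119 were 5, 8, 1, 1 and 1 without plots 1, 2, 11, 12 and 13. Root calls at day 119 were 93, 84, 77, 68, 19, 25, 62 and 38 without plots 1, 2, 11, 12, 13, 17, 18 and 20, and 1734 at day 91 without plot 17 and 2032 without plot 12. At day 77 they were 832 and 905 without plots 13 and 17, and at day 84 they were 627, 738 and 843 without plots 12, 17 and 18. Other settings gave more root calls at day 119, with 799 from only the groups compared, 290 by edgeR and 282 with a pseudocount of 10, where leaves had 1, 6 and 6. At day 91 only the groups compared gave 347 in leaves and 1632 in roots, and a block of neighbouring plots 1710 in leaves, while at day 84 that block gave 546 leaf genes and edgeR 671. Root CYP79A1 at day 84 lost its call without plot 12 (adjusted p = 0.0533). Leaf UGT85B1 lost its call without plot 1, 5, 6, 13, 14, 19 or 20 (adjusted p up to 0.133) and CYP71E1 without plot 5, 6, 13, 19 or 20 (up to 0.0988), both also with 1 mean per plot (0.0687 and 0.0605) and CYP71E1 without day 70 (0.0641), while for root DHN1 edgeR gave a like change of 1.78 without a call (adjusted p = 1), since DHN1 was 0 in all 3 RTX430 control roots at day 105 and a combination without any read leaves edgeR's log mean free.

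In leaves, drought after flowering raised DHN1 and lowered RbcS, PPDK and PHYB. Over days 70 to 119 DHN1 averaged 3324 ± 1553 normalized counts in droughted RTX430 plots against 10.5 ± 1.37 in control, and 2261 ± 1926 against 61.5 ± 32 in BTX642 (SD, n = 3 plots each). Its mean log2 change was 6.35 (SE 0.36; limma, adjusted p = 1.12e-32). P5CS2 rose by 1.15 (SE 0.15) and VIN1 by 1.24 (SE 0.38). RbcS fell by 0.58 (SE 0.11), the C4 carbonic anhydrase CA by 0.47 (SE 0.13) and PPDK by 0.59 (SE 0.11). PHYB fell by 1.23 (SE 0.09; limma, adjusted p = 8.42e-24), PRR37 by 1.02 (SE 0.19), CN15 by 1.43 (SE 0.26), CN12 by 1.40 (SE 0.25) and CN8 by 1.32 (SE 0.35). DW3, an auxin exporter that sets plant height, fell by 0.85 (SE 0.17). The lignin enzyme CAD2 rose in leaves by 0.78 (SE 0.23). By list, 1 of 4 carbon fixation genes fell (PPDK), 1 of 3 dhurrin genes fell (CYP79A1, by 0.97, SE 0.37) and 1 of 3 clock genes fell (GI, by 0.21, SE 0.08), each by both adjustments. Set against all other genes no list passed (camera, adjusted p = 0.694 for each of the 3). Calls were lost without 1 plot for VIN1 (plots 19 and 20, adjusted p = 0.0715 and 0.0957), CYP79A1 (11, 20, 21 or 22, up to 0.176) and GI (2, 11, 12, 15 or 16, up to 0.102), and without day 70 for CAD2 (0.0716). With 1 mean per plot VIN1 (0.259), CA (0.168), PPDK (0.159), CYP79A1 (0.0969) and GI (0.115) lost theirs, edgeR did not call CYP79A1 (0.138), and CN8 (0.0504), CYP79A1 (0.146) and GI (0.0881) lost their calls with only the compared groups. With a pseudocount of 10 the change of CYP79A1 was −0.45 (adjusted p = 0.209).

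The largest leaf rise after flowering besides DHN1 was in Sobic.003G292400 (chromosome 3, 62488685 to 62493225), at 6.50 (SE 0.38). The largest falls were in Sobic.009G204900 (chromosome 9, 55341679 to 55346555), which fell by 5.24 (SE 0.24), and Sobic.006G060800 (chromosome 6, 41262480 to 41264491), which fell by 4.53 (SE 0.33). Of 19945 genes limma called 10238, 5682 higher and 4556 lower, and 1973 changed at least 2-fold (860 higher, 1113 lower). The share of higher genes among the calls, 55.5%, became 51% after median-of-ratios rescaling, and edgeR called 6004 higher and 5724 lower. The reported count of calls became 6536 with 1 mean per plot. At day 63, before the assigned start of this drought, limma called 0 leaf genes between postflowering and control plots, with 164 at a raw p under 0.05, and edgeR called 0. Without plot 16 limma called 1. Calls numbered 3183 at day 70, or 1710 without plot 15 and 1609 with only the groups compared, and 6874 at day 77.

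In roots, drought after flowering raised DHN1 in both genotypes. It averaged 2170 ± 1151 normalized counts against 6.18 ± 3.49 in RTX430 and 10900 ± 5477 against 61.1 ± 57.9 in BTX642 (SD, n = 3 plots each), a mean log2 change of 8.43 (SE 0.34; limma, adjusted p = 1.66e-45). P5CS2 rose by 2.64 (SE 0.11). The lignin enzymes 4CL and CCoAOMT fell by 0.89 (SE 0.09) and 0.40 (SE 0.14). PPDK fell by 1.56 (SE 0.15) and NADP-MDH rose by 1.11 (SE 0.11), the members of the carbon fixation list that passed, by both adjustments. RbcS rose by 0.65 (SE 0.21). In the same roots, 105 of 194 genes enriched in leaves over roots rose and 21 fell, with a median of 0.55. Among the dhurrin genes UGT85B1 rose by 0.40 (SE 0.18), 1 of 3 over all genes and 0 adjusted over the list alone. That mean averages called changes of opposite sign: at day 77 UGT85B1, CYP79A1 and CYP71E1 fell by 1.10 (SE 0.34), 1.49 (SE 0.52) and 0.99 (SE 0.28), and at day 119 they rose by 1.52 (SE 0.34), 1.66 (SE 0.52) and 0.93 (SE 0.28), where CYP79A1 lost its call with only the groups compared (adjusted p = 0.0506). Of the clock genes LHY rose by 0.29 (SE 0.12) and TOC1 fell by 0.26 (SE 0.11), by both adjustments. Set against all other genes no list passed (camera, adjusted p = 0.853 for each of the 3). Calls were lost without 1 plot for CCoAOMT (plot 3, 4, 19 or 20, adjusted p up to 0.139), UGT85B1 (1, 2, 3, 4, 11, 12 or 21, up to 0.175), LHY (3, 4, 19 or 20, up to 0.191) and TOC1 (3, 11, 12, 15, 16, 19 or 20, up to 0.191). With 1 mean per plot they also failed, at 0.251, 0.148, 0.166 and 0.146, as did CCoAOMT (0.0628), UGT85B1 (0.106) and TOC1 (0.0522) with only the groups compared. Without day 70 UGT85B1 (0.0577), LHY (0.0589) and TOC1 (0.101) were not called, nor were CCoAOMT (0.0615) and LHY (0.105) with the ages of 1 plot per group included, or UGT85B1 without the libraries of low depth or mixed genotype (0.0782).

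After DHN1, the largest root rise after flowering was in Sobic.007G109800 (chromosome 7, 39655862 to 39656846), at 7.76 (SE 0.34). The largest falls were in Sobic.010G113600 (chromosome 10, 11963589 to 11965019), which fell by 6.75 (SE 0.40), and Sobic.004G021500 (chromosome 4, 1669748 to 1670351), which fell by 6.62 (SE 0.37). Of 22039 genes limma called 14059, 5898 higher and 8161 lower, while edgeR called 7727 higher and 7565 lower. Among the genes that changed at least 2-fold, 813 were higher and 2953 lower. At day 63 limma called 0 root genes, with 250 at a raw p under 0.05, and edgeR called 0. Calls numbered 7803 at day 70 and 11449 at day 77.

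**Figure D2:**
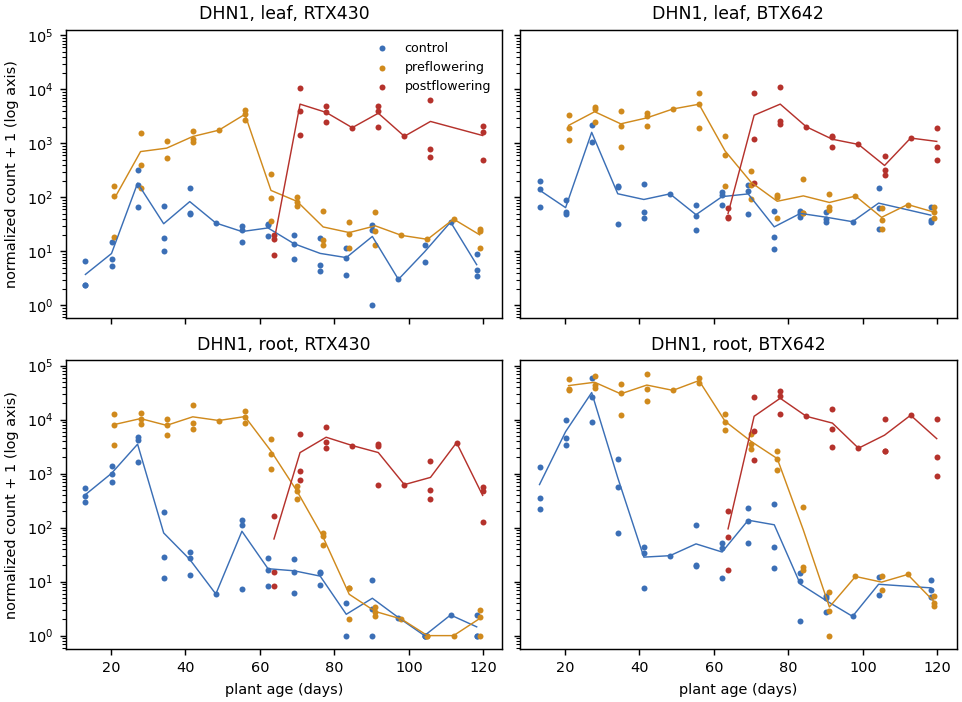
DHN1 normalized count plus 1 (log axis) in each library against plant age in days, by tissue and genotype, with points for libraries and lines through the mean of each age, for control, preflowering and postflowering plots. Root DHN1 in control RTX430 plots averages 3501 at day 28 and 24.7 at day 42, and in preflowering plots 11372 at day 56.

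After flowering, the leaf responses of PPDK, NADP-MDH and DHN1 differed between the genotypes. Leaf PPDK fell from 455927 ± 69140 to 235690 ± 86290 normalized counts in RTX430 and stood at 347974 ± 61328 against 379135 ± 14476 in BTX642 (SD, n = 3 plots each). The difference of the log2 changes, RTX430 minus BTX642, was −0.95 (SE 0.23; limma, adjusted p = 0.00287). NADP-MDH differed by −0.72 (SE 0.18), and DHN1 by 3.59 (SE 0.71; limma, adjusted p = 1.96e-04), with a change of 8.14 in RTX430 and 4.56 in BTX642. For DHN1 the control level, 10.5 ± 1.37 normalized counts in RTX430 and 61.5 ± 32 in BTX642, enters this difference, and the droughted levels overlap, at 3324 ± 1553 and 2261 ± 1926. Of the 4 carbon fixation genes 2 differed over all genes and 3 adjusted over the list alone, all lower in RTX430. That list passed against all other genes with the preset correlation (camera, adjusted p = 9.29e-04) but not with an estimated one (adjusted p = 0.0784). The largest differences were in Sobic.004G157100 (chromosome 4, 49817844 to 49821068), at 4.21 (SE 0.64), and Sobic.003G097800 (chromosome 3, 8617949 to 8619145), at −4.21 (SE 0.37). In all 1471 genes differed, 1306 of them with the larger change in RTX430 and 552 with opposite signs in the genotypes. Over the 1973 leaf genes that changed at least 2-fold, the median signed change was 1.77 in RTX430 and 1.13 in BTX642. Other splits of the plots, with the mean drought change taken out, called as many genes in 15 of 100 cases, and in 2 of 32 with plots exchanged only within sets of neighbouring plot numbers (2592 genes, highest other 3095), so chance is not excluded for this count. It was 3039 without plot 3 and 642 without plot 16, 2797 with a block of neighbouring plots, 2873 by edgeR, 3229 without a block, 268 with only the groups compared and 903 with days 70, 77 and 91. With 1 mean per plot it was 106, and the calls of PPDK (adjusted p = 0.649), NADP-MDH (0.343) and DHN1 (0.0674) were lost, as were those of PPDK (0.276) and NADP-MDH (0.116) with only the groups compared, while edgeR gave Sobic.003G097800 −4.17 without a call (adjusted p = 1, a combination without any read).

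In roots after flowering CYP79A1 fell in RTX430 and rose in BTX642. It averaged 1669 ± 912 normalized counts under drought and 2780 ± 400 under control in RTX430, and 4405 ± 1565 against 1083 ± 204 in BTX642 (SD, n = 3 plots each). The log2 changes were −1.29 (SE 0.38) and 1.84 (SE 0.39), a difference of −3.13 (SE 0.55; limma, adjusted p = 1.52e-05). By genotype 2 of 3 dhurrin genes fell in RTX430 (CYP79A1, and CYP71E1 by 0.51, SE 0.21) and 3 of 3 rose in BTX642 (CYP71E1 by 0.56, SE 0.21), and against all other genes the list passed in neither (camera, adjusted p = 0.577 and 0.116). UGT85B1 differed by −1.45 (SE 0.36) and CYP71E1 by −1.08 (SE 0.30). All 3 dhurrin genes differed, by both adjustments, and the list passed against all other genes (camera, adjusted p = 1.61e-05) and with an estimated correlation (adjusted p = 0.00877). P5CS2 differed by 0.77 (SE 0.22). The largest differences were in Sobic.008G009400 (chromosome 8, 695725 to 696627), at 4.19 (SE 0.46), and Sobic.006G011900 (chromosome 6, 1729206 to 1730517), at −4.90 (SE 1.04). In all 1432 root genes differed, 1147 with the larger change in RTX430. Here 10 of 100 splits called as many genes, so these do not exclude chance for the count, and 1 of 32 did with plots exchanged only within sets of neighbouring plot numbers (2272 genes, highest other 2087). The reported count was 893 without plot 20, where UGT85B1 (adjusted p = 0.0621), CYP71E1 (0.11) and P5CS2 (0.0727) lost their calls, as did CYP71E1 without plot 21 (0.0549), P5CS2 without plot 2 (0.106) and CYP79A1 in RTX430 without plot 22 (0.0908). CYP71E1 lost its call in RTX430 without plot 12, 16 or 20 (up to 0.291) and in BTX642 without plot 2, 4, 11 or 21 (up to 0.132). With the ages of 1 plot per group included, the change of CYP79A1 in RTX430 was −0.55 (adjusted p = 0.243) and that of CYP71E1 −0.14 (0.605), and the differences of UGT85B1 and CYP71E1 were −0.96 (0.118) and −0.73 (0.168), none called. With only the groups compared CYP79A1 in RTX430 (0.0889), CYP71E1 in RTX430 (0.128) and the differences of UGT85B1 (0.0691), CYP71E1 (0.133) and P5CS2 (0.19) were not called. By edgeR the count was 2552, without a block 2682 and with only the groups compared 414. With 1 mean per plot it was 205, and CYP79A1 (0.0595), UGT85B1 (0.191), CYP71E1 (0.194) and P5CS2 (0.0685) were not called, nor was CYP71E1 in RTX430 (0.0963) or BTX642 (0.0861), while edgeR gave Sobic.008G009400 4.67 and Sobic.006G011900 −4.75 without a call (adjusted p = 1 for both, each with a combination without any read).

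**Figure D3:**
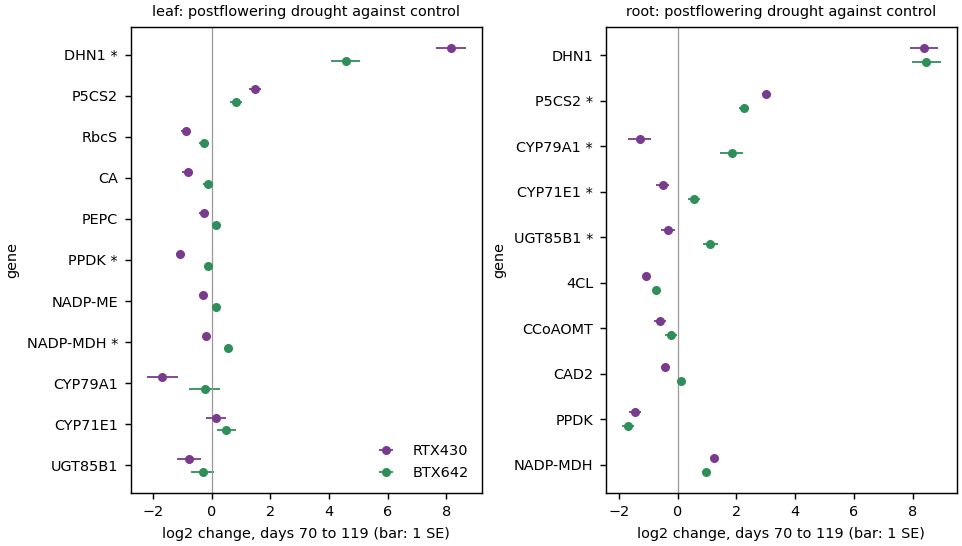
Log2 change under postflowering drought against control over days 70 to 119 in RTX430 and BTX642, for named genes in leaf and root, with points for the fitted change and bars for 1 SE. A star marks genes whose changes differed between the genotypes, such as root CYP79A1, at −1.29 in RTX430 and 1.84 in BTX642.

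Before flowering the genotypes differed in fewer leaf genes. The leaf differences were largest in Sobic.008G183400 (chromosome 8, 61702527 to 61711466), at 2.81 (SE 0.32) for RTX430 minus BTX642, and Sobic.010G130800 (chromosome 10, 17958306 to 17960450), at −3.22 (SE 0.46). In total 59 leaf genes differed, 40 with the larger change in BTX642, and 947 passed a raw p under 0.05. In roots PPDK fell less in RTX430, a difference of 1.17 (SE 0.30; limma, adjusted p = 0.00595). The largest root differences were in Sobic.009G021300 (chromosome 9, 1905208 to 1906028), at 3.66 (SE 0.60), and Sobic.004G036100 (chromosome 4, 2908913 to 2912284), at −6.45 (SE 0.72). In all 1288 root genes differed, 650 with the larger change in RTX430 and 638 in BTX642. The leaf count was 31, 33, 39, 33, 39 and 39 without plots 13, 14, 17, 18, 19 and 20, and the root count 714 and 809 without plots 17 and 20. Other settings gave more leaf genes, 125 with a pseudocount of 10, 121 with only the groups compared, 159 with a block of neighbouring plots, 212 by edgeR and 294 without a block. The last 3 gave 1989, 2449 and 2492 in roots, and 1 mean per plot gave 746. Root PPDK lost its call without plot 11 (adjusted p = 0.0713) and with 1 mean per plot (0.11), and edgeR gave Sobic.010G130800 −2.66 and Sobic.009G021300 2.88 without a call (adjusted p = 1 for both, each with a combination without any read).

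Leaves shared 3147 genes higher and 2328 lower under both droughts, among them DHN1 and P5CS2 (higher) and RbcS, PHYB, PRR37, CN8, CN12, CN15 and PPDK (lower). Independent lists of these sizes would share 1325 and 812.7, and unchanged groups simulated against the same control plots, with lists of these sizes taken from the top-ranked genes, shared 1831 and 1193. Across genes, the covariance of the changes was 0.225 against 0.00588 in the simulation. In roots 4333 genes were higher and 5123 lower under both, among them DHN1, P5CS2 and NADP-MDH (higher) and 4CL, CCoAOMT and PPDK (lower), against 2306 and 3047 for independent lists and 2773 and 3559 simulated. The root covariance was 0.558 against 0.00358. The droughts were compared with different libraries of the same control plots, so part of the excess may come from those plots. Between the tissues, 2825 genes were higher and 2261 lower in both leaves and roots before flowering, of 18815 tested in both, and 2699 and 2457 after flowering. Leaves and roots came from the same plots, so these counts are not set against chance.

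Under control watering the genotypes differed most in Sobic.001G064200 (chromosome 1, 4831163 to 4835634), which was higher in RTX430 by 11.93 in leaves (SE 0.27) and 11.50 in roots (SE 0.34), and in Sobic.004G240600 (chromosome 4, 58863134 to 58868190), at −10.74 in leaves (SE 0.17) and −10.93 in roots (SE 0.18). GHD7, a repressor of flowering in long days, was higher in RTX430 leaves by 2.52 (SE 0.31; limma, adjusted p = 2.76e-12). DHN1 was lower in RTX430, at −2.45 in leaves (SE 0.41) and −1.74 in roots (SE 0.38). P5CS2 was also lower, at −1.11 in leaves (SE 0.17), though not called with 1 mean per plot (adjusted p = 0.0676). VIN1 was higher in RTX430 roots by 1.62 (SE 0.24). In all 7927 leaf genes and 11187 root genes were called. A gene whose sequence in RTX430 or in BTX642 differs from the reference genome can lose reads in alignment, so a difference in this comparison can be one of sequence.

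From days 14 to 28 to days 91 to 119 of the control plots, leaf CYP79A1 fell by 6.17 (SE 0.36), UGT85B1 by 2.62 (SE 0.27) and CYP71E1 by 2.93 (SE 0.23). NADP-MDH fell by 1.84 (SE 0.09), RbcS by 1.79 (SE 0.11), NADP-ME by 0.95 (SE 0.09), PPDK by 0.81 (SE 0.11) and PEPC by 0.77 (SE 0.11). CN15 rose by 3.64 (SE 0.25) and EHD1 by 3.17 (SE 0.25). All 4 carbon fixation and all 3 dhurrin genes fell in leaves by both adjustments. Each list passed with the preset correlation (camera, adjusted p = 0.00886) but not with an estimated one (adjusted p = 0.129). In roots DHN1 fell by 9.27 (SE 0.37), VIN1 by 4.25 (SE 0.24) and CYP79A1 by 3.90 (SE 0.29), and PPDK rose by 4.39 (SE 0.16) and TOC1 by 2.68 (SE 0.11). Root DHN1 averaged 0.454 normalized counts in RTX430 control plots at day 119, so its log2 change depends on the pseudocount. It also depends on day 28 among the young days, when control root DHN1 averaged 31599 in BTX642 and 3501 in RTX430, against 625 and 407 at day 14. In all 15109 leaf genes and 18186 root genes were called. The median of all root genes was 0.11 as deposited and −0.03 after rescaling, the largest such shift, and root changes with age are to be read against it. Each age was sampled on its own date of a single season, so changes with age cannot be told apart from changes with date, such as day length or weather.

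On chromosome 7, a run of 24 neighbouring tested root genes fell together under both droughts as the mean of genotypes. The run spans 6992974 to 7535757, from Sobic.007G065800 to Sobic.007G066908, and holds 27 gene models. Under drought before flowering all 24 fell, with a median of −3.88 (lowest −4.36, highest −1.25), from a mean of 296 normalized counts in control plots to 13.4. After flowering all 24 fell again, with a median of −1.55, and 24 rose with age under control (median 4.34). In BTX642 alone all 24 fell under each drought, and in RTX430 alone 23 fell before flowering (highest 0.38) and 22 after (highest 0.22). From day 56 to day 63 in preflowering plots 23 rose (median 3.68). In RTX430 18 were higher than in BTX642 and 1 lower under control. In windows of 10 consecutive tested genes, 10 of 10 were called and at least 2-fold lower here, and the largest window in 1000 shuffles of the calls held 9 (permutation p = 0.001, the smallest the shuffles can give). Adjacent gene models may be copies that share reads, and such sharing was not analysed here.

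**Figure D4:**
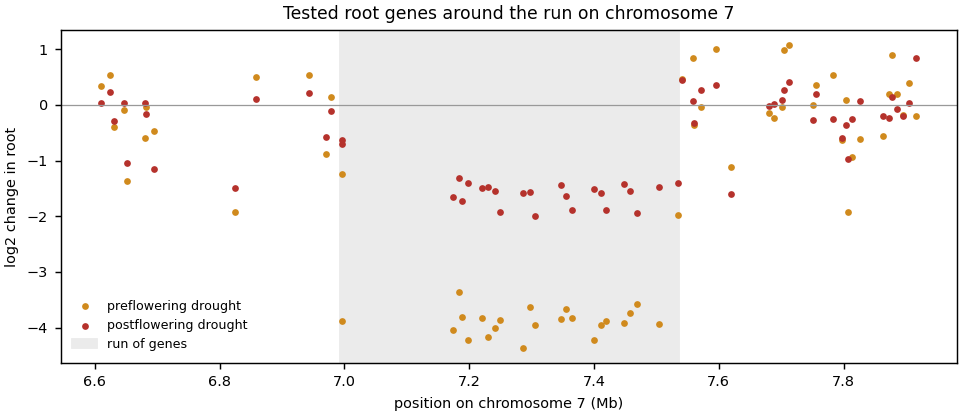
Log2 change of tested root genes against position on chromosome 7 in megabases, under preflowering and postflowering drought, with the run of genes shaded. The 24 genes of the run lie between −4.36 and −1.25 before flowering.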

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

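The tests that weigh the 3 patterns here, and the look at days with 1 plot per group, were chosen after the result was seen, whereas the tests of the difference between genotypes and the splits across all plot numbers were planned.

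The change under drought differed between RTX430 and BTX642, by a test of the difference itself, for 1471 leaf genes and 1432 root genes after flowering and for 59 leaf genes and 1288 root genes before flowering. Among named genes, the differences after flowering (RTX430 minus BTX642, log2) were 3.59 for DHN1, whose control level was lower in RTX430, −0.72 for NADP-MDH and −0.95 for PPDK in leaves. In roots they were −3.13 for CYP79A1, −1.45 for UGT85B1, −1.08 for CYP71E1 and 0.77 for P5CS2. Before flowering the difference was 1.17 for PPDK in roots. Leaving out 1 plot moved the leaf count after flowering to 642 (plot 16) or 3039 (plot 3), the root count to 893 (plot 20), the root count before flowering to 714 (plot 17) or 809 (plot 20), and the leaf count before flowering to 31 to 39 (plots 13, 14, 17, 18, 19 and 20). A block of neighbouring plots gave 2797 leaf genes after flowering, and 159 leaf and 1989 root genes before it, and without a block these were 3229, 294 and 2492, and 2682 in roots after flowering. Leaving out 1 plot also ended the calls of UGT85B1, CYP71E1 and P5CS2 without plot 20 (limma, adjusted p = 0.0621, 0.11 and 0.0727), of CYP71E1 without plot 21 (0.0549), of P5CS2 without plot 2 (0.106) and of PPDK in roots without plot 11 (0.0713). With 1 mean per plot all these named differences lost their calls (adjusted p from 0.0595 for CYP79A1 to 0.649 for leaf PPDK), and the counts after flowering were 106 in leaves and 205 in roots. Other splits of the plots gave as many genes after flowering in 15 of 100 cases in leaves and 10 of 100 in roots, and within sets of neighbouring plot numbers in 2 of 32 and 1 of 32.

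Over the 1973 leaf genes changed at least 2-fold after flowering, the median signed change was larger in RTX430 than in BTX642 by 0.66. Thinning each of 195 libraries to 10 M reads left a difference of 0.66, which argues against depth as the cause, and median-of-ratios rescaling left 0.65, which argues against the scaling. A single plot does not carry it either: with each plot left out in turn the difference ran from 0.52 without plot 16 to 0.89 without plot 3. The genotypes' starting levels do not carry it as a whole: at equal control levels, a line through these genes gave 0.75, and 0.60 without plot 16, the lowest. A difference in response between the genotypes and a difference in how dry their 3 plots each became stay open, since other splits of the plots gave as many genes in 15 of 100 cases, and in 2 of 32 within sets of neighbouring plot numbers.

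After day 63, leaves of the preflowering plots differed from control along the change that control leaves undergo with age, in the opposite direction. Across genes, which are not independent replicates, the difference correlated with the age change of the other genotype at −0.55 as the mean of genotypes (two-sided exact test over 400 exchanges of regimes among the 6 plots of each genotype, p = 0.005, the smallest they can give). In roots the correlation was −0.45 (−0.61 in RTX430 and −0.29 in BTX642; exact p = 0.01). With the drought change it was −0.04 in leaves (exact p = 0.405) and 0.11 in roots (exact p = 0.3), so a lasting drought response can neither be shown nor excluded. The exchanges were made in each genotype independently, although the RTX430 and BTX642 plots of a regime carry neighbouring numbers. Exchanged together, such plots would leave too few arrangements for a p under 0.05. These p-values therefore hold only if plots with neighbouring numbers are independent. A candidate explanation is that the plants of these plots were later in development. The age change of the control plots also holds the change of sampling date, so it does not stand for development alone. Chance is not excluded for the count of leaf genes, since 8 of 100 planned splits of the plots called as many. Within sets of neighbouring plot numbers it was 1 of 32, the smallest share possible, in a test added after the planned splits.

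A root library of BTX642 under preflowering drought (day 35, plot 6) had a genotype score of 0.395, where 0 stands for BTX642 and 1 for RTX430, while other BTX642 roots lay between −0.0291 and 0.0426 and RTX430 roots between 0.9 and 1.04. A wrong label is argued against by BTX642-only genes, of which 29 of 29 were above 0. A library made only of a first-generation plant of a cross is argued against by the RTX430 share, below the equal share of such a plant. That share was estimated at 24.6% with an interval ending at 27.6% (95%, 2000 bootstraps over genes). Other kinds of cross, or a crossed plant among several sampled, were not tested. RTX430-only genes were above 0 for 69 of 70, on 10 chromosomes with medians between 0.155 and 0.258 of their RTX430 level. Material of both genotypes in 1 library, from the field or from the bench, stays open. These values cannot tell it apart from crossed plants among those sampled.

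Other libraries stood apart by the same score, by less. In leaves BTX642 under preflowering drought (day 56, plot 17) had 0.143, where the next BTX642 leaf library had 0.0439. Control RTX430 plot 20 at day 21 had 0.884 in leaves and 0.9 in roots, where the next RTX430 libraries had 0.963 and 0.949. What set these libraries apart was not tested.

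On days with 1 plot per group, left out of the windows, DHN1 stood above all control libraries of the same genotype and tissue after day 28 in preflowering plots at day 49 and in postflowering plots at days 98 and 112. At day 49 it read 1752 normalized counts in preflowering RTX430 leaves and 4329 in BTX642 leaves (highest control 149 and 178), and 9606 and 34730 in roots (highest control 197 and 1869). In postflowering leaves it read 1350 in RTX430 and 954 in BTX642 at day 98, and 1253 in BTX642 at day 112. In postflowering roots it read 623 and 3742 in RTX430, and 2949 and 12028 in BTX642, at days 98 and 112. In preflowering plots at days 98 and 112, after the days assigned to their drought, it did not: it read 18.8 and 38.6 in RTX430 leaves, 105 and 72.7 in BTX642 leaves, 1.03 and 0 in RTX430 roots and 11.4 and 12.5 in BTX642 roots. These values have no replicate check. Control libraries up to day 28 are not in this comparison. At day 28 they reached 59395 in BTX642 roots, 4776 in RTX430 roots, 2149 in BTX642 leaves and 314 in RTX430 leaves. Of the drought values, only those of RTX430 leaves and the day 49 values of RTX430 roots and BTX642 leaves exceeded these.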

How the results depend on the processing

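The fits without the doubted libraries, with days 70, 77 and 91 only and with windows of 20 genes, and the splits within sets of plots, were chosen after the result was seen, and the other alternatives were planned. The directions of the 160 gene values followed held in every alternative that was run, since 0 of them changed sign. The alternatives share most of their libraries, so few changes of sign could arise. Of these values, 48 of 74 in leaves and 67 of 86 in roots also kept their side of the threshold in all alternatives. Of the counts over all genes, 607 of the values under an alternative lay within 1.5 times the reported count and 53 did not. For named genes 171 values under an alternative lost the call and 3429 kept their side of the threshold, and of the counts per age and the shares 84 moved and 747 did not. Depth limits single libraries, the lowest at 1.87 M reads in leaves and 3.67 M in roots, and leaving out the doubted ones moved no count by over 1.5 times. The cause was not tested unless one is named.

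Plot was a random block in the reported fit. Without a replicate block, which treats libraries of 1 plot as independent, leaf counts were 6155 for RTX430 before flowering (3573 reported), 3763 for the later days (1665), 7716 for BTX642 after flowering (5044), 11953 for genotype under control (7927), and 294 (59) and 3229 (1471) for the genotype differences before and after flowering. In roots the last pair were 2492 (1288) and 2682 (1432). With a replicate block of neighbouring plot numbers added to the plot, leaf counts were 5856 for RTX430 before flowering, 3126 for the later days and 159 and 2797 for the genotype differences, and the root difference before flowering was 1989. Calls on whole reads with edgeR, which had no block, were 6447 in RTX430 and 7986 in BTX642 leaves before flowering (5178 reported in BTX642), 3581 for the later days, 212 and 2873 for the leaf genotype differences and 2449 and 2552 for the root ones. For drought itself edgeR called 10382 leaf and 17553 root genes before flowering and 11728 and 15292 after. It gave a p near 1 to some genes that limma called, because a combination of genotype, regime and age without any read leaves its log mean free: 109 leaf and 277 root genes before flowering, all with such a combination, among them Sobic.001G369200.

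With 1 mean per plot the plot is the unit of the test, which also leaves far fewer degrees of freedom. Leaf counts after flowering were then 6536 for the mean of genotypes (10238 reported), 5309 in RTX430 (8837), 1800 in BTX642 and 106 for the genotype difference. In roots the genotype differences were 746 before and 205 after flowering. Whether the unit or the degrees of freedom lowered these counts was not tested. With only the libraries of the groups compared, leaf counts were 5559 in RTX430 before and 5398 after flowering, 121 and 268 for the genotype differences, and 414 for the root difference after flowering. A pseudocount of 10 gave 125 for the leaf difference before flowering, and days 70, 77 and 91 gave 903 for the leaf difference after flowering. With an estimated correlation 2 of the 8 passing lists passed, and on ranks 9 lists passed, 7 of them the same. Over all comparisons 100 members of lists were called over all genes and 106 adjusted over the list alone.

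With each plot left out in turn, leaf counts ran from 1757 (plot 13) to 3391 for RTX430 before flowering, with 2143 and 1855 without plots 12 and 18, from 3025 (plot 17) to 5154 for BTX642 before flowering, and from 31 (plot 13) to 60 for their difference, with 33, 39, 33, 39 and 39 without plots 14, 17, 18, 19 and 20. They ran from 1907 (plot 14) to 3598 at day 63, from 1107 (plot 13) to 1999 on the later days, from 3111 (plot 15) to 5482 for BTX642 after flowering, and from 642 (plot 16) to 3039 (plot 3) for the difference after flowering. Postflowering leaves at day 63 went from 0 to 1 (plot 16; limma, with 164 genes at a raw p under 0.05 in the reported fit and 0 by edgeR). Root differences ran from 714 (plot 17), with 809 without plot 20, to 1615 before flowering and from 893 (plot 20) to 1966 after flowering.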

Other observations

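The test of the day 28 control plots and the choice of the regions were made after the result was seen; the splits of the plots across all plot numbers were set before.

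Genes beyond those described above also moved. In roots before flowering DW1, a regulator of internode length, rose by 0.78 (SE 0.10; limma, adjusted p = 2.53e-12), and from day 56 to day 63 its difference from control fell by 1.22 (SE 0.26). The difference of TST2 fell by 0.91 (SE 0.23) over the same days. In leaves after flowering GHD7 fell by 0.73 (SE 0.26), and PHYC, a red-light receptor, rose by 0.21 (SE 0.07). Leaving out 1 plot ended the calls of GHD7 (plots 1 and 15; limma, adjusted p = 0.0771 and 0.0524) and PHYC (plots 1, 2 and 16; 0.0713, 0.0759 and 0.06), and both failed with only the groups compared (0.0581 and 0.0713), as did PHYC with 1 mean per plot (0.231).

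Other runs of neighbouring genes appeared in leaves under drought and in both tissues between the genotypes. In leaves, on chromosome 6 between 4263845 and 4678325, 7 of 10 consecutive tested genes were called and at least 2-fold lower after flowering (permutation p = 0.005, 1000 shuffles), with a median of −2.39. On chromosome 6 between 57407187 and 57442937, 6 of 10 were lower before flowering (permutation p = 0.001, the smallest the shuffles can give), with a median of −1.31. Under control, 8 of 10 genes on chromosome 5 between 5329587 and 5503980 were lower in RTX430 roots (permutation p = 0.001, the smallest the shuffles can give). In RTX430 leaves 8 of 10 were lower on chromosome 10 between 12677438 and 12937350 (permutation p = 0.001). There 7 of 10 were higher on chromosome 3 between 6792224 and 6942567 (permutation p = 0.002). These are the fullest windows of their comparisons, and neighbouring copies that share reads were not looked for.

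DHN1 in control plots was highest at day 28. In roots it averaged 31599 ± 25568 normalized counts in BTX642 and 3501 ± 1661 in RTX430 at day 28, against 5971 ± 3417 and 1008 ± 326 at day 21 and 836 ± 926 and 78.6 ± 103 at day 35 (SD, n = 3 plots each). A hypothesis is that the control plots may have been drier at day 28. Its test took the genes changed at least 2-fold after flowering in the other genotype, and asked whether each control plot moved along that change at day 28 against the mean of days 21 and 35. The signed median averaged 0.38 in roots (SD 0.17), higher in 6 of 6 plots (two-sided exact permutation of signs, p = 0.0312, the smallest that 64 arrangements can give). In leaves it averaged 0.71 (SD 0.11), higher in 5 of 5 plots (exact p = 0.0625, the smallest that 32 arrangements can give, so the design cannot reach 0.05). The signs were changed for each plot on its own, though the control plots of the genotypes carry neighbouring numbers. Changed together, such plots would leave too few arrangements for a p under 0.05. Other causes that raise these genes, such as heat or the hour of sampling, were not tested.

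Other splits of the plots into groups of the same sizes were refitted, 100 of 200 possible ones where both genotypes enter, with the correlation of plots estimated from fewer genes, so the real counts differ a little from those above. In leaves the real split called the most genes, 1 of 100 splits, for drought before flowering (7805 genes, highest other 5268), day 63 (3043, 1030), the change from day 56 to day 63 (6272, 1923), drought after flowering (9937, 8479) and the genotype difference before flowering (48, 25). In roots the same held for drought before flowering (16945, 13707), day 63 (7752, 5133), the change (11634, 6821), the later days (5493, 1118), drought after flowering (14196, 11940) and the genotype difference before flowering (1399, 421). The highest other splits for the drought comparisons mostly exchanged 1 plot of the real groups. The RTX430 and BTX642 plots of a regime carry neighbouring numbers, but the splits exchanged the plots of each genotype independently. Exchanged together, such plots would leave too few splits for a share under 0.05. These shares therefore exclude chance only if plots with neighbouring numbers are independent.

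For 3 further comparisons the shares themselves do not exclude chance, by splits that ignore the order of the plot numbers. Splits gave as many genes in 8 of 100 cases for leaves on the later days of preflowering plots (1457 genes, highest other 4052), in 15 of 100 for the leaf genotype difference after flowering (1254, 6657) and in 10 of 100 for the root one (1550, 5206). In the last pair of comparisons the mean drought change was taken out first. Splits that call several times the real count point to a structure of the samples: the plots of 1 group differ among themselves. Postflowering plots at day 63 called 0 genes, which all 100 splits reached in both tissues, with up to 1437 genes in leaves and 1482 in roots.

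Plot numbers 1 to 6, 11 to 16 and 17 to 22 each hold 1 plot of every genotype and regime, and the splits above exchange plots across these sets, so differences between sets enter them. A further test, chosen after the result was seen, exchanged plots only within a set, with the sets in the model, which gives 32 splits. For the later days of preflowering plots in leaves 1 of 32 splits gave as many genes (2901, highest other 973). For the root genotype difference after flowering it was also 1 of 32 (2272, 2087). The real split thus called the most genes in both, for roots by a small margin. A share of 1 of 32 is the smallest these splits can give. The test was added after the planned splits had left chance open, so it does not exclude chance for these comparisons. For the leaf genotype difference after flowering 2 of 32 splits gave as many genes (2592, 3095), and chance is not excluded. Postflowering plots at day 63 called 0 genes in all 32 splits of both tissues.

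Within 1 genotype, 10 splits are too few for a share under 0.05. The real and highest other counts were 3212 and 70 in RTX430 leaves and 4804 and 0 in BTX642 leaves before flowering, and 8528 and 6043, and 4677 and 2716, after flowering. In roots they were 14708 and 1874, and 14678 and 2282, before flowering, and 12937 and 2726, and 10362 and 3565, after flowering. For genotype under control they were 7462 and 2223 in leaves and 11516 and 807 in roots, again with 10 splits. Exchanging young and old ages within control plots gave 1 of 32 arrangements for age in both tissues (15135 genes and highest other 13095 in leaves, 18172 and 16211 in roots). That is the smallest share these arrangements can give. It excludes chance only if control plots with neighbouring numbers are independent, and it cannot tell age from the date of sampling.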
